A study of Mus musculus with 20 samples.

How the data were processed

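Single limbs of mouse embryos (129Sv) at embryonic day 13.5 were profiled by the submitters on Affymetrix GeneChip ST arrays from total RNA with a biotin label. The deposited values are intensities, made with RMA per the submitters' processing notes, 1 value per probe set and array. The values themselves settle the scale: they run from 1.65 to 13033 with array medians from 28.6 to 31.8, so they are linear intensities and not log2 values, and probe sets are not centred. The software version, the annotation and the genome build are not given in the sources used here. Scanner files were not used here, so background treatment, probe filtering and the dates on which the arrays were run stay unknown. The log2 was taken here, with no pseudocount, and array medians then ranged from 4.84 to 4.99.

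The table held 35512 probe sets, of which 1 was empty on every array. Of the rest, 21789 carried 1 gene symbol, 1621 carried several and 12101 were not in the gene table, and the last 2 kinds were left out of the gene tests. Of the named probe sets, 21698 were named through an Entrez gene identifier and 3 through an accession, with RefSeq genes on GRCm38.p6, 88 kept the platform's name, and 2 symbols were updated. The assembly served only for names and for which gene lies next to which. Where a gene had more than 1 probe set, as 1001 genes did, the probe set with the highest mean over all arrays stood for it, which left 19936 genes. No 2 arrays held identical values.

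Samples were grouped by genotype and limb type as the labels give them, 5 arrays in each of 4 groups. The labels also give the side and a number in each description. That number cannot mark single embryos, since 4 of the 6 sets of arrays with 1 genotype and 1 number held both sexes. The titles call the arrays biological replicates, but the labels do not say that the limbs came from separate embryos, so the p-values measure only the spread between these limbs, some of which may share an embryo. The arrays' number limits the precision. Sex was read from Kdm5d, Uty, Eif2s3y and Xist.

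All comparisons came from 1 fit in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with a constant prior) with 4 group means, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. They were knockout against wild type over both limb types (the mean of both genotype effects), in forelimbs and in hindlimbs, the difference between those effects, hindlimb against forelimb in wild type and in knockouts, and left against right with side added to the groups. Array counts beside a change are arrays beyond the range of the group compared with, within a limb type or genotype. The overlap expected for independent lists is the product of the list lengths divided by the number of genes. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

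There were 30 gene lists with 620 entries, 31 of them without a probe set: axon guidance and neurotrophic factors; BMP, GDF and TGF-beta pathway; cartilage; cell cycle; dorsoventral limb patterning; early-stage genes; endothelium; epidermis and apical ridge; erythroid; FGF and hedgehog pathway; fibrillar and network collagens; growth plate hypertrophy; hair follicle, nail and pad; Hox genes 9 to 13; hypoxia and glycolysis; immediate early and stress; joint interzone; limb-type identity; macrophage and leukocyte; muscle connective tissue; neuron; osteoblast and perichondrium; pericyte and smooth muscle; podocyte genes tied to Lmx1b; Schwann cell and peripheral nerve; sex-linked; skeletal muscle; small leucine-rich proteoglycans; tendon and ligament; and Wnt pathway. Each was tested with camera (limma, preset correlation 0.01), adjusted over the lists, and genes were counted past the threshold over all genes and adjusted over the list alone. The groups, tests, lists and the rule for naming genes were set before the data were examined.

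Genes were named by rule. The rule took Lmx1b, the 10 raised and 10 lowered genes with the largest changes past the threshold for the genotype over both limb types (same sign in both) and for limb type in wild type, and 5 and 5 for the forelimb, hindlimb and knockout limb-type comparisons. It also took the 5 smallest p for the difference between effects and for side, up to 4 members of each described list with the smallest p, and members asked for by a check (sex-linked and limb-type identity genes, Wnt7a, En1). Provisional names and probe sets with several symbols were skipped.

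The pipeline was tested on simulated data, with changes of 0.3, 0.6 and 1.2 on the log2 scale put into 67, 67 and 66 genes. For the genotype over both limb types it recovered 73.1%, 100% and 100% of them, and 4.3% of calls were unchanged genes. In forelimbs it recovered 35.8%, 83.6% and 100%, with 4.6% of calls unchanged. In hindlimbs it recovered 41.8%, 92.5% and 100%, and for limb type in wild type 35.8%, 98.5% and 100%, each with 7.1% of calls unchanged. The simulated noise was independent between genes and arrays, without sex, shared embryos or correlated genes. These rates therefore check the fit and need not hold for the real arrays.

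The alternatives tried were quantile normalisation again, centring each array on its median, leaving out genes whose highest group mean lay under the 40th percentile, testing all probe sets, averaging the probe sets of a gene, a trended robust prior, array weights, a fixed block by title number or by side and description number, a random block by description number, and averaging limbs by that number. Others were covariates for side, the Y-linked level and the mean of the skeletal muscle list, a fit with only 1 limb type, adjusted p under 0.01, a minimum of 1.5-fold, camera with an estimated correlation, fry, and leaving out each array in turn. Added after seeing the data were a covariate for the first axis of variation within groups (genes with mean log2 over 6), the 13 male arrays only, and a fit without 2 knockout arrays. For other splits, 100 divisions of the arrays were drawn with a fixed seed, and neighbouring genes were compared with 10000 random placements.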

Results

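Gene expression was measured in single limbs dissected from mouse embryos at embryonic day 13.5, on Affymetrix whole-transcript arrays. Lmx1b encodes a LIM-homeodomain transcription factor made in dorsal limb mesenchyme, where it sets dorsal identity. The mutants lacked Lmx1b, and the series title gives the question as which limb genes the factor controls. The 20 arrays fell into 4 groups of 5: wild-type forelimbs, wild-type hindlimbs, knockout forelimbs and knockout hindlimbs. The median intensity per array ranged from 28.6 to 31.8, and 19936 genes were tested. The titles call the arrays biological replicates but do not say that the limbs came from separate embryos, so p-values measure the spread between these arrays. Y-linked transcripts and Xist, the RNA that coats the inactive X chromosome, set 13 male arrays apart from 7 female ones. The mean of 3 Y-linked genes was at least 6.89 on the log2 scale in the male arrays and at most 2.71 in the female ones. All 5 wild-type forelimbs were male, whereas 3 of the 5 knockout forelimbs were female. Each hindlimb group held 3 male and 2 female arrays.

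Lmx1b itself, measured by probe set 10481835, was lower in knockout limbs. Its log2 level was 6.30 ± 0.127 (SD, n = 5) in wild-type forelimbs and 5.72 ± 0.079 (SD, n = 5) in knockout forelimbs. In hindlimbs it was 6.45 ± 0.083 (SD, n = 5) in wild type and 5.92 ± 0.114 (SD, n = 5) in knockouts. Every knockout array, at 5.6 to 6.1, lay below every wild-type array, at 6.14 to 6.52. Across both limb types Lmx1b fell by 0.55 on the log2 scale (SE 0.049; limma, adjusted p = 2.63e-07). Whether the probes lie within the deleted part of the gene was not analysed here, so the residual signal cannot be read as intact transcript.

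In limbs without Lmx1b, the extracellular matrix gene Kera fell most, to a level 7.89-fold below wild type. Kera encodes keratocan, a small leucine-rich proteoglycan that binds collagen fibrils. It fell by 2.98 on the log2 scale (SE 0.103; limma, adjusted p = 2.64e-14), and all 10 knockout arrays lay below the wild-type arrays of their limb type. Apod, which encodes the lipid carrier apolipoprotein D, fell by 1.42 (SE 0.073, adjusted p = 4.84e-11). The homeobox transcription factor Emx2 fell by 1.32 (SE 0.092, adjusted p = 7.77e-09). The calcium-binding protein gene Calb1 fell by 1.32 (SE 0.103), the secreted synaptic organiser gene Cbln2 by 1.22 (SE 0.074), and Lum, which encodes the proteoglycan lumican, by 1.18 (SE 0.099). The iron exporter gene Slc40a1 fell by 1.09 (SE 0.098), and a, the agouti gene of pigment signalling, by 1.05 (SE 0.095). For each of these 8 genes, all 10 knockout arrays lay below the wild-type arrays of their limb type. Ibsp, which encodes bone sialoprotein, fell by 1.30 (SE 0.241, adjusted p = 0.00424), with 6 arrays below that range.

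**Figure D1:**
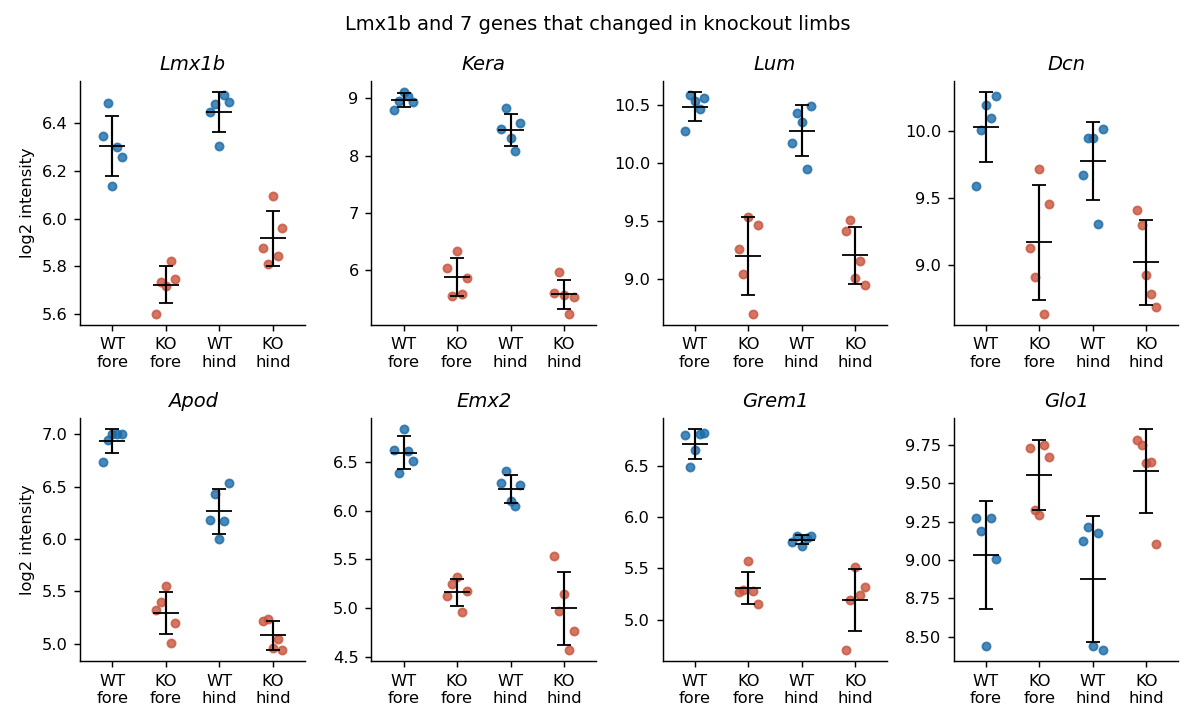
Log2 intensity of Lmx1b, Kera, Lum, Dcn, Apod, Emx2, Grem1 and Glo1 on each array (dots), with the mean and SD of each group of 5 arrays; wild type is blue and knockout is red. In both limb types every knockout array lies below the wild-type arrays for Lmx1b, Kera, Lum, Apod, Emx2 and Grem1, while Glo1 was higher by 0.61 on average.

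Fewer genes rose in the knockout limbs, and their changes were smaller. Hpse2, a heparanase relative that binds heparan sulfate, rose by 0.69 on the log2 scale (SE 0.091; limma, adjusted p = 8.16e-05). Glo1, which encodes the methylglyoxal-detoxifying enzyme glyoxalase, rose by 0.61 (SE 0.128, adjusted p = 0.0116). Its spread within groups was wide, at an SD of 0.324, and its call was lost with the muscle list as a covariate and when limbs sharing a number in the descriptions were averaged. The neurite growth factor gene Nrn1 rose by 0.58 (SE 0.094), the lymphatic growth factor gene Vegfd by 0.54 (SE 0.119) and the transcriptional cofactor gene Eya1 by 0.53 (SE 0.088). Lix1 rose by 0.44 (SE 0.084), the chromatin protein gene Hmgb1 by 0.44 (SE 0.081), the transcription factor gene Rfx4 by 0.43 (SE 0.053) and the carbonic anhydrase gene Car14 by 0.42 (SE 0.086). Rfx4 was the 1 of these in which all 10 knockout arrays lay above the wild-type arrays of their limb type.

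Several skeletal and connective tissue genes fell. Of 13 measured genes of osteoblasts and perichondrium, the cell layer that wraps cartilage, 5 fell and none rose, and 9 fell when adjusted over the list alone. Their median change was -0.26 (camera, adjusted p = 9.14e-10), a call that held with an estimated correlation (adjusted p = 0.00739). Besides Ibsp, they included Ostn, which encodes the secreted peptide osteocrin and fell by 0.60 (SE 0.111), and Alpl, the alkaline phosphatase gene of mineralising cells, which fell by 0.33 (SE 0.068). Of 17 tendon and ligament genes, 5 fell and 1 rose, and 7 fell when adjusted over the list alone (median -0.14; camera, adjusted p = 3.42e-08; adjusted p = 0.0256 with an estimated correlation). Thbs4, a tendon matrix thrombospondin gene, fell by 0.92 (SE 0.118), and the fibril-associated collagen genes Col14a1 and Col12a1 fell by 0.75 (SE 0.158) and 0.62 (SE 0.097). These 2 lists were the only 2 of the 18 called by camera in this comparison that held with an estimated correlation.

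Of 26 fibrillar and network collagen genes, 7 fell and none rose, and 13 fell when adjusted over the list alone. Camera called this list lower (median -0.16, adjusted p = 4.53e-10), but the adjusted p = 0.104 with an estimated correlation. The collagen genes Col5a2 and Col3a1 fell by 0.44 (SE 0.086) and 0.37 (SE 0.077). Of 16 small leucine-rich proteoglycan genes, Kera, Lum and Dcn, which encodes decorin, fell and none rose, and 4 fell when adjusted over the list alone. Dcn fell by 0.81 (SE 0.132; limma, adjusted p = 0.00116). The list as a whole was called lower by camera (adjusted p = 4.23e-07; adjusted p = 0.111 with an estimated correlation). Of 12 genes of growth plate hypertrophy, 3 fell and none rose, and 6 fell when adjusted over the list alone (camera, adjusted p = 1.52e-07; adjusted p = 0.059 with an estimated correlation). The 3 were Ibsp, Alpl and Sp7, a transcription factor gene of bone-forming cells that fell by 0.30 (SE 0.065). None of 22 cartilage genes passed the test, also when adjusted over the list alone (camera, adjusted p = 0.0164; adjusted p = 0.565 with an estimated correlation). That call was lost without wild-type forelimb replicates 1 (0.0717) or 2 (0.133), knockout forelimb replicate 2 (0.101) or knockout hindlimb replicate 6 (0.211).

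Some genes for nerve guidance also fell. Of 41 axon guidance and neurotrophic genes, 7 fell and 1 rose, and 11 fell and 2 rose when adjusted over the list alone. Camera called the list lower (median -0.06, adjusted p = 0.000149; adjusted p = 0.183 with an estimated correlation). Nrp2, a semaphorin co-receptor gene, fell by 0.55 (SE 0.062; limma, adjusted p = 1.22e-05). Gfra1, a receptor gene for the neurotrophic factor GDNF, fell by 0.41 (SE 0.060), and the repulsive cue genes Sema3c and Sema3a fell by 0.39 (SE 0.064) and 0.26 (SE 0.043). Of 14 neuron genes, 3 fell and 1 rose, and 4 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.00832; adjusted p = 0.059 with an estimated correlation). Gap43, a growth cone gene, fell by 0.40 (SE 0.047), and Dcx, a microtubule-binding gene of migrating neurons, fell by 0.40 (SE 0.053).

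Several signalling genes changed while their pathways as lists did not. Grem1, a secreted BMP antagonist gene, fell by 0.99 (SE 0.077; limma, adjusted p = 4.12e-08), in all 10 knockout arrays, and the ligand gene Bmp2 rose by 0.36 (SE 0.073). Of 35 BMP, GDF and TGF-beta genes, 2 fell and 1 rose, and 5 fell and 3 rose when adjusted over the list alone (camera, adjusted p = 0.106). The secreted ligand gene Wnt11 fell by 0.40 (SE 0.040, adjusted p = 1.88e-06), and Rspo3, an enhancer of Wnt signalling, fell by 0.28 (SE 0.054). They were the 2 of 40 Wnt pathway genes that passed the test, as also when adjusted over the list alone (camera, adjusted p = 0.403). Of 17 dorsoventral patterning genes, Lmx1b and Emx2 fell and Bmp2 rose, and 4 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.126). Wnt7a, the dorsal ectoderm signal that induces Lmx1b, did not pass the test (log2 change 0.02, SE 0.088, adjusted p = 0.952). En1, a repressor of Wnt7a in ventral ectoderm, did not pass either (log2 change -0.09, SE 0.061, adjusted p = 0.526).

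Some markers of other tissues fell too. Of 39 skeletal muscle genes, 6 fell and none rose, and 22 fell when adjusted over the list alone. Camera called the list lower (median -0.19, adjusted p = 6.62e-13; adjusted p = 0.183 with an estimated correlation). The troponin gene Tnnt2 fell by 0.41 (SE 0.076) and the sarcomere gene Actn2 by 0.43 (SE 0.096). Of 20 macrophage and leukocyte genes, 2 fell, and 9 fell when adjusted over the list alone (camera, adjusted p = 1.52e-07; adjusted p = 0.111 with an estimated correlation). They were Mrc1, a scavenger receptor gene that fell by 0.43 (SE 0.087), and Csf1r, the colony-stimulating factor receptor gene, which fell by 0.27 (SE 0.060). Of 20 endothelial genes, 3 fell, and 6 fell when adjusted over the list alone (camera, adjusted p = 9.58e-07; adjusted p = 0.244 with an estimated correlation). These were Tek, a vessel receptor gene that fell by 0.44 (SE 0.068), Prox1, a lymphatic transcription factor gene that fell by 0.56 (SE 0.109), and Emcn, which fell by 0.29 (SE 0.062).

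In all, 406 genes differed between genotypes across both limb types, 93 higher and 313 lower in knockouts (limma, adjusted p under 0.05). Of these, 48 changed at least 1.5-fold and 116 had a mean log2 level under 5. Among 58 named genes, 16 kept their call in every alternative fit that tested them and without any single array: a, Apod, Calb1, Cbln2, Emx2, Eya1, Gap43, Grem1, Hpse2, Kera, Lmx1b, Lum, Nrp2, Rfx4, Slc40a1 and Wnt11. Adjusted p under 0.01, the 1.5-fold minimum and the fit of all probe sets were not applied to single genes. The count fell to 266 without wild-type forelimb replicate 3, 260 without wild-type hindlimb replicate 7 and 269 without wild-type hindlimb replicate 10. It was 67 with the 13 male arrays only, 111 with the muscle list as a covariate, 106 when limbs sharing a number in the descriptions were averaged, 255 after centring each array on its median and 768 with array weights. With the muscle list as a covariate, camera no longer called the endothelium and neuron lists, nor the muscle list, which its own mean as the covariate brings about by construction. With the male arrays only, camera no longer called the neuron list.

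Serpinb10 and Lhx9 lost their calls in many fits that left out 1 array. Serpinb10, a serpin gene, fell by 1.15 on the log2 scale (SE 0.299; limma, adjusted p = 0.0478) and lost its call in 16 of 20 fits that left out 1 array (adjusted p from 0.0584 to 0.0998). It kept the call only without wild-type forelimb replicate 1, wild-type hindlimb replicate 9, knockout forelimb replicate 3 or knockout hindlimb replicate 7. Lhx9, a LIM-homeodomain gene of the distal limb, rose by 0.44 (SE 0.109, adjusted p = 0.036) and lost its call in 10 of the 20 fits (adjusted p from 0.0545 to 0.0805). The arrays were wild-type forelimb replicates 3 and 5, wild-type hindlimb replicates 7, 8 and 10, knockout forelimb replicates 2 and 4, and knockout hindlimb replicates 8, 9 and 10.

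In forelimbs alone, Kera, the bone gene Ibsp and the lipid carrier gene Apod fell most among genes without a provisional name. Kera fell by 3.09 on the log2 scale (SE 0.146; limma, adjusted p = 1.61e-11), an 8.52-fold difference. Ibsp fell by 2.40 (SE 0.341, adjusted p = 0.000351), from 6.05 ± 1.2 (SD, n = 5) in wild type, with all 5 knockout forelimbs below the wild-type ones. Apod fell by 1.65 (SE 0.103), Thbs4 by 1.55 (SE 0.166), Cbln2 by 1.52 (SE 0.105), Emx2 by 1.42 (SE 0.130) and Grem1 by 1.40 (SE 0.109). Nrn1 rose by 0.88 (SE 0.133), Hpse2 by 0.79 (SE 0.129) and Car14 by 0.62 (SE 0.121). Lhx9 rose by 0.70 (SE 0.154, adjusted p = 0.0231), and its adjusted p was 0.0813 without wild-type forelimb replicate 3, 0.0736 without wild-type forelimb replicate 5 and 0.0877 without knockout forelimb replicate 4. Eya1 rose by 0.61 (SE 0.124, adjusted p = 0.0123), and its adjusted p was 0.05 without wild-type forelimb replicate 5 and 0.0503 without knockout forelimb replicate 4.

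By list, 5 of 13 osteoblast genes fell in knockout forelimbs and 9 fell when adjusted over the list alone (camera, adjusted p = 2.45e-13). Of 17 tendon genes, 5 fell and 1 rose, with 10 lower and 1 higher when adjusted over the list alone (camera, adjusted p = 3.6e-10). Of 12 growth plate genes, 4 fell (8 adjusted over the list alone), and of 26 collagen genes 7 fell (14 adjusted over the list alone). None of 17 Hox genes of groups 9 to 13 passed over all genes, but 7 rose when adjusted over the list alone (median 0.20; camera, adjusted p = 2.2e-05). Camera called 16 of the 30 lists, and these held with an estimated correlation: osteoblast (adjusted p = 0.00137), tendon (0.00975), growth plate (0.029), collagen (0.048), Hox (0.048) and neuron (0.048). Of 39 muscle genes 6 fell, and 27 fell when adjusted over the list alone (median -0.31; camera, adjusted p = 1.06e-20; adjusted p = 0.0902 with an estimated correlation). The muscle list averaged 7.33 ± 0.186 (SD, n = 5) in wild-type and 6.99 ± 0.144 (SD, n = 5) in knockout forelimbs, and sex also differed between these groups, as given above. On the first axis of variation within groups, wild-type forelimbs averaged 5.904 ± 6.66 (SD, n = 5) and knockout forelimbs -0.192 ± 5.762 (SD, n = 5). Within groups, the Hox list followed that axis with r = -0.86, collagen 0.753, tendon 0.577, osteoblast 0.559 and muscle 0.52. Growth plate (0.213) and neuron (0.042) followed it little. Changes of the former lists in forelimbs may therefore partly reflect a difference along this axis.

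The forelimb comparison called 253 genes, 48 higher and 205 lower in knockouts (limma). The count was 436 without wild-type forelimb replicate 1, 136 without replicate 3, 133 without replicate 4 and 124 without replicate 5 of that group, and 164 and 124 without knockout forelimb replicates 2 and 4. It was 139 with the Y-linked level as a covariate, 37 with the male arrays only, 42 with the muscle list as a covariate, 151 with the main axis of variation within groups as a covariate, and 163 when the forelimb arrays were fitted alone.

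In hindlimbs alone, Kera, Emx2, Apod and Grem1 were again lower in knockouts, while the bone gene Ibsp and the tendon gene Thbs4 did not pass the test. Kera fell by 2.87 on the log2 scale (SE 0.146; limma, adjusted p = 7.29e-11), Emx2 by 1.22 (SE 0.130), a by 1.22 (SE 0.134), Apod by 1.19 (SE 0.103), Calb1 by 1.17 (SE 0.145) and Lum by 1.08 (SE 0.140). In each, all 5 knockout hindlimbs lay below the 5 wild-type ones. Grem1 fell by 0.59 (SE 0.109, adjusted p = 0.0145), with an adjusted p = 0.0524 without wild-type hindlimb replicate 10. Wnt11 fell by 0.45 (SE 0.057), Nrp2 by 0.50 (SE 0.088) and Gap43 by 0.41 (SE 0.067). Ibsp changed by -0.21 (SE 0.341, adjusted p = 0.99) and Thbs4 by -0.30 (SE 0.166, adjusted p = 0.92), and the tests of their difference from the forelimb change gave adjusted p = 0.34 and 0.0808. Both genes were already lower in wild-type hindlimbs than in wild-type forelimbs, as given below. The peptide hormone gene Edn2 was the 1 gene that rose, by 0.31 (SE 0.064, adjusted p = 0.0426). It lost its call in 15 of 20 fits that left out 1 array (adjusted p from 0.0542 to 0.154), and kept it without wild-type forelimb replicates 1 or 5, wild-type hindlimb replicate 8, knockout forelimb replicate 5 or knockout hindlimb replicate 7.

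Of the lists, 2 of 16 proteoglycan genes fell in knockout hindlimbs, and 3 when adjusted over the list alone (camera, adjusted p = 3.08e-05; adjusted p = 0.247 with an estimated correlation). Of 41 axon guidance genes 1 fell, and 8 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.00151; adjusted p = 0.312 with an estimated correlation). None of 39 muscle genes passed, also when adjusted over the list alone (median -0.06; camera, adjusted p = 0.065), and the list averaged 6.74 ± 0.156 (SD, n = 5) in wild type and 6.68 ± 0.135 (SD, n = 5) in knockouts. None of 13 osteoblast, 12 growth plate or 26 collagen genes passed, with 0, 0 and 1 lower when adjusted over the list alone (camera, adjusted p = 0.0266, 0.0589 and 0.00617). Of 17 tendon genes 1 fell, also 1 when adjusted over the list alone (camera, adjusted p = 0.00404). The osteoblast call was lost without wild-type hindlimb replicate 7, 8 or 10 or knockout hindlimb replicate 6, 9 or 10 (0.0597 to 0.0915). The collagen call was lost without wild-type hindlimb replicate 8 (0.0614) or knockout hindlimb replicate 9 (0.0974). Camera called 14 of the 30 lists, and none held with an estimated correlation (adjusted p of at least 0.247). The hindlimb comparison called 46 genes, 1 higher and 45 lower (limma), with 13 from the male arrays only and 82 with array weights.

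**Figure D2:**
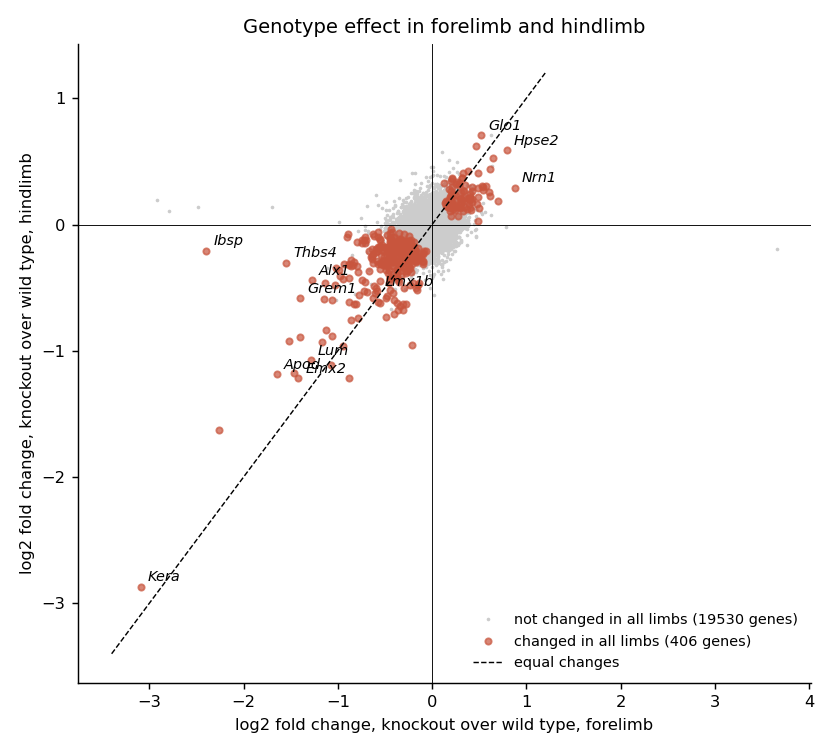
Log2 change, knockout minus wild type, in forelimbs (horizontal) and hindlimbs (vertical), 1 point per gene; the 406 genes changed across both limb types are red, the other genes grey, and the dashed line marks equal change. The changed genes, chosen on the mean of both effects, have the same sign in both limb types, and 299 of them lie nearer to 0 in hindlimbs.

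Most genes called between genotypes in forelimbs moved the same way in hindlimbs. Of the 205 genes lower in knockout forelimbs and the 45 lower in knockout hindlimbs, 37 were shared, where independent lists would share 0.463. Of the 253 genes called in forelimbs, 237 had the same sign in hindlimbs, and over all 19936 genes 12483 did, with a correlation across genes of r = 0.459, although genes are not independent replicates. The 406 genes called on the mean of both effects, a choice that favours equal signs, all had the same sign in each (r = 0.821). The hindlimb change was smaller for 299 of these 406, and the median ratio of hindlimb to forelimb change was 0.696. The difference itself passed the test for 4 genes, each more reduced in knockout forelimbs. For Grm7, a metabotropic glutamate receptor gene, the effects differed by 0.81 (SE 0.117; limma, adjusted p = 0.0138), with changes of -0.91 (SE 0.083) in forelimbs and -0.10 (SE 0.083) in hindlimbs. Alx1, a homeobox gene of limb and face mesenchyme, changed by -1.27 (SE 0.092) and -0.44 (SE 0.092), a difference of 0.83 (adjusted p = 0.0197). Pax1, a paired-box gene of the shoulder girdle region, changed by -0.49 (SE 0.075) and 0.18 (SE 0.075), a difference of 0.66 (adjusted p = 0.0197). Cntn1, a neural cell adhesion gene, changed by -0.90 (SE 0.1) and -0.07 (SE 0.1), a difference of 0.82 (adjusted p = 0.0435). Grm7 and Cntn1 had low mean log2 levels (3.95 and 4.17), under the median of every array.

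By list, camera found the osteoblast genes more reduced in knockout forelimbs than in knockout hindlimbs (adjusted p = 6.39e-10), and this 1 call of 13 held with an estimated correlation (adjusted p = 0.00624). The same test for the muscle list gave adjusted p = 9.44e-17, and adjusted p = 0.17 with an estimated correlation. The osteoblast and muscle lists were already lower in wild-type hindlimbs than in wild-type forelimbs (medians -0.43 and -0.57). So was Alx1, as given below. A low starting level in hindlimbs was therefore not told apart from a smaller genotype effect there. Of the 4 genes, only Grm7 kept its call without any single array, and the count was 0 with the male arrays only, with the muscle covariate or with all probe sets tested. It was also 0 with a fixed block by side and description number, although those numbers do not pair the arrays. Alx1 lost its call (adjusted p from 0.0565 to 0.0639) without wild-type forelimb replicate 3, wild-type hindlimb replicates 7, 8 or 10, or knockout hindlimb replicate 7. Pax1 lost it (0.0528 to 0.0657) without any of these 5 arrays, wild-type forelimb replicates 4 or 5, or knockout forelimb replicate 2. Cntn1 lost it in 15 of 20 fits (0.0565 to 0.131), and kept it without wild-type forelimb replicate 1, knockout forelimb replicates 3 or 4, or knockout hindlimb replicates 8 or 9. The count was 10 without wild-type forelimb replicate 1, 2 without wild-type forelimb replicates 4 or 5 or knockout forelimb replicate 2, and 1 without wild-type forelimb replicate 3, wild-type hindlimb replicates 7, 8 or 10, or knockout hindlimb replicate 7.

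**Figure D3:**
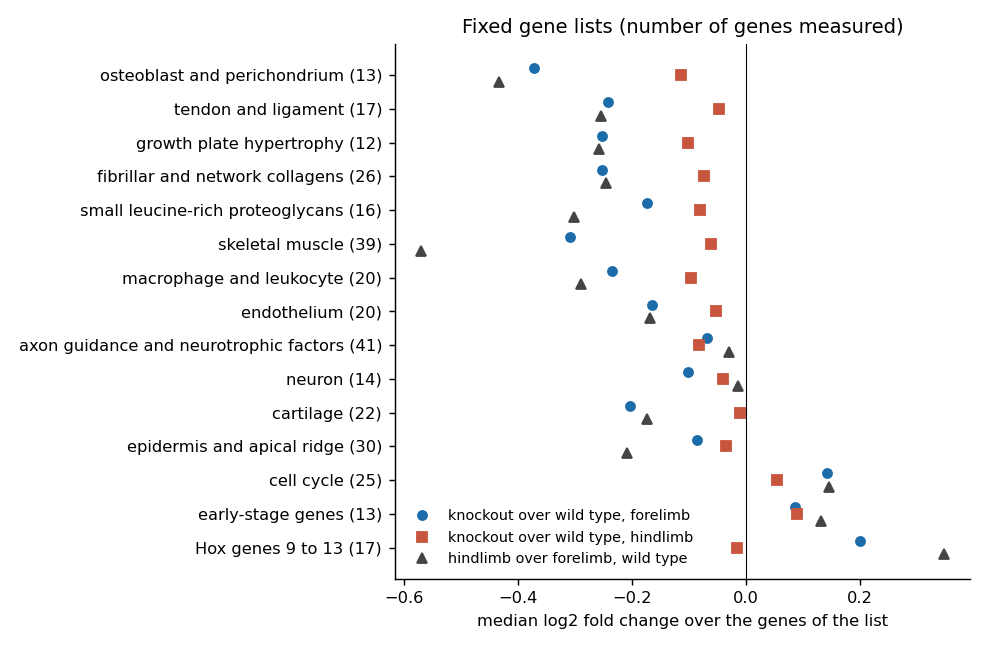
Median log2 change of 15 gene lists for knockout minus wild type in forelimbs (circles) and hindlimbs (squares) and for hindlimb minus forelimb in wild type (triangles). The muscle list sits at -0.31, -0.06 and -0.57 and the osteoblast list at -0.37, -0.11 and -0.43.

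Wild-type hindlimbs and forelimbs differed most in Tbx5 and Pitx1, which mark forelimb and hindlimb. This comparison does not set limb-type identity apart from maturity or sex, since all 5 forelimbs were male and 2 of the 5 hindlimbs were female. Tbx5, the forelimb T-box gene, fell by 3.77 on the log2 scale in hindlimbs, a 13.7-fold difference (SE 0.115; limma, adjusted p = 9.09e-16). Pitx1, a homeobox gene that sets hindlimb identity, was 8.51-fold higher, a rise of 3.09 (SE 0.087, adjusted p = 3.61e-16). The hindlimb T-box gene Tbx4 rose by 1.71 (SE 0.116) and Isl1, a LIM-homeodomain gene needed for hindlimb initiation, rose by 1.17 (SE 0.108). Posterior Hox genes of the C cluster rose, Hoxc10 by 1.75 (SE 0.123), Hoxc11 by 1.47 (SE 0.1) and Hoxc9 by 0.56 (SE 0.070), while the anterior gene Hoxc5 fell by 1.59 (SE 0.276). In all of these, the 5 hindlimb arrays lay apart from the 5 forelimb arrays. The microRNA gene Mir196a-1 rose by 0.88 (SE 0.083) from a low level, 2.84 ± 0.171 (SD, n = 5) in forelimbs. The retinoic acid synthesis gene Aldh1a2 rose by 1.36 (SE 0.252), the transcription factor gene Sox2 by 1.05 (SE 0.107), the pigment enzyme gene Dct by 0.81 (SE 0.183) and Car14 by 0.70 (SE 0.121).

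**Figure D4:**
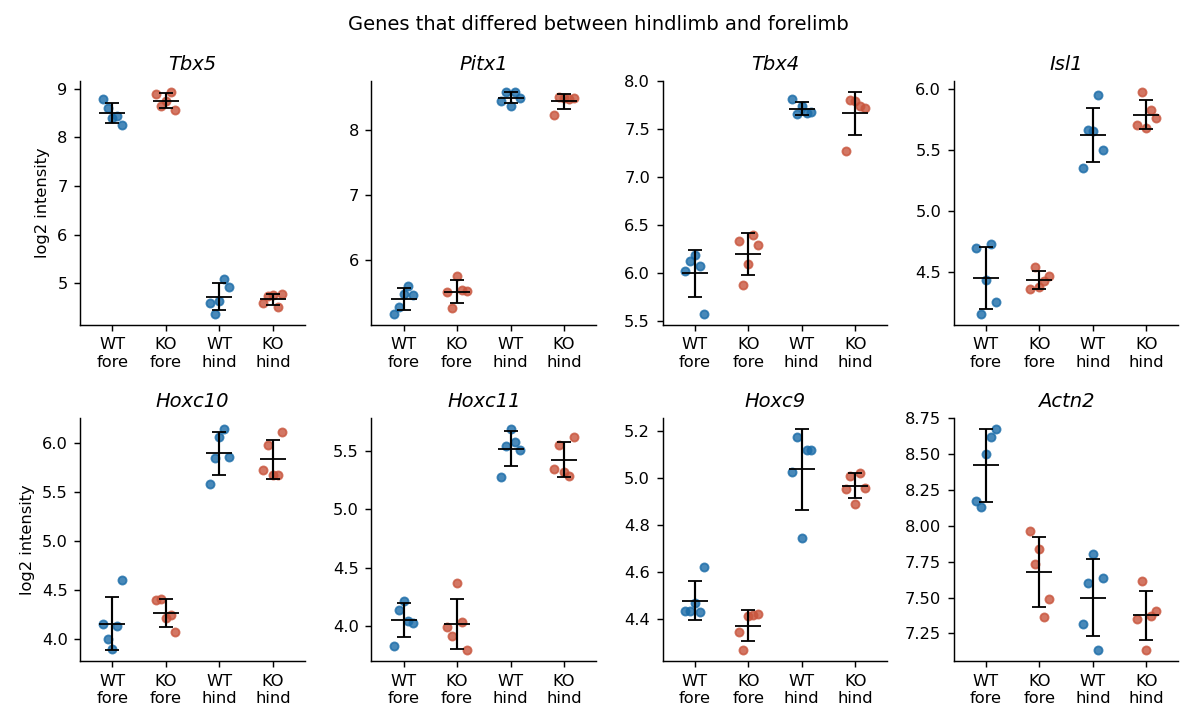
Log2 intensity of Tbx5, Pitx1, Tbx4, Isl1, Hoxc10, Hoxc11, Hoxc9 and Actn2 on each array (dots), with the mean and SD of each group of 5 arrays; wild type is blue and knockout is red. From forelimbs to hindlimbs, Tbx5 fell by 3.77 in wild type and fell by 4.08 in knockouts, while Pitx1 rose by 3.09 and 2.92.

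Muscle and bone genes were lower in wild-type hindlimbs. Of 39 muscle genes, 34 fell and none rose, and 36 fell when adjusted over the list alone (median -0.57; camera, adjusted p = 1.14e-44; adjusted p = 0.0205 with an estimated correlation). The myosin gene Myh8 fell by 1.28 (SE 0.234), Actn2 by 0.92 (SE 0.136), the sarcomere-associated gene Klhl41 by 0.72 (SE 0.099) and the acetylcholine receptor gene Chrng by 0.53 (SE 0.079). Of 13 osteoblast genes, 7 fell, 8 when adjusted over the list alone (camera, adjusted p = 3.11e-09; adjusted p = 0.00977 with an estimated correlation). Ibsp fell by 2.20 (SE 0.341), and Phex, an endopeptidase gene of phosphate balance, fell by 2.03 (SE 0.191). Of 17 tendon genes, 4 fell, 9 when adjusted over the list alone, with Thbs4 lower by 1.60 (SE 0.166) and Col14a1 by 1.29 (SE 0.223). The dermal matrix gene Dpt fell by 1.45 (SE 0.236), Alx1 by 1.42 (SE 0.092) and Rtl3, a retrotransposon-derived gene, by 1.32 (SE 0.169). Of 20 macrophage genes, 5 fell, 12 when adjusted over the list alone, and of 12 pericyte genes 4 fell, 9 when adjusted over the list alone.

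Of 17 Hox genes of groups 9 to 13, 6 rose and 1 fell, and 10 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 1.11e-07; adjusted p = 0.0205 with an estimated correlation). Of 13 genes typical of earlier stages, 4 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.000451; adjusted p = 0.0634 with an estimated correlation). Among them Hmga2, a chromatin gene of growing embryonic tissue, rose by 0.69 (SE 0.112) and Msx1, a homeobox gene of limb mesenchyme, by 0.64 (SE 0.122). Of 25 cell cycle genes, 2 rose, 6 when adjusted over the list alone (camera, adjusted p = 1.39e-06; adjusted p = 0.323 with an estimated correlation). Camera called 18 of the 30 lists in this comparison, and 8 held with an estimated correlation: muscle, osteoblast, Hox, tendon (adjusted p = 0.0226), growth plate (0.0372), limb-type identity (0.0441), macrophage (0.0441) and pericyte (0.0478). In the limb-type list, 7 of 16 genes rose and 4 fell, with 8 and 6 when adjusted over the list alone. In all, 650 genes differed, 154 higher and 496 lower in hindlimbs (limma). The count was 374, 381 and 340 without wild-type forelimb replicates 3, 4 and 5, and 354 and 311 without wild-type hindlimb replicates 6 and 9. It was 232 with the axis of variation within groups as a covariate, 419 with male arrays only, 427 with all probe sets tested and 1260 with array weights.

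Knockout hindlimbs and forelimbs differed in the main limb-type identity genes, while fewer muscle and bone genes passed the test than in wild type. Tbx5 fell by 4.08 (SE 0.115; limma, adjusted p = 3.59e-16) and Pitx1 rose by 2.92 (SE 0.087, adjusted p = 6.08e-16). Hoxc10 rose by 1.57 (SE 0.123), Tbx4 by 1.46 (SE 0.116), Sox2 by 1.41 (SE 0.107), Hoxc11 by 1.40 (SE 0.1) and Isl1 by 1.36 (SE 0.108). Phex fell by 1.87 (SE 0.191), the receptor gene Gpr50 by 1.46 (SE 0.169) and Dpt by 1.31 (SE 0.236). Col14a1 fell by 1.02 (SE 0.223, adjusted p = 0.0334) and lost its call without any of knockout forelimb replicates 1, 2 and 3 or knockout hindlimb replicates 8, 9 and 10 (adjusted p from 0.0757 to 0.121). Of 39 muscle genes 5 fell, and 25 fell when adjusted over the list alone (median -0.32; camera, adjusted p = 9.55e-23; adjusted p = 0.217 with an estimated correlation). Of 13 osteoblast genes 1 fell, also 1 when adjusted over the list alone (camera, adjusted p = 0.379). Camera called 14 lists and none held with an estimated correlation. For limb-type identity, 6 of 16 genes rose and 3 fell (7 and 5 adjusted over the list alone), and its median (-0.07) was negative while its mean (0.14) and camera's direction were positive (adjusted p = 0.00432; adjusted p = 0.217 with an estimated correlation).

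The comparison called 123 genes, 35 higher and 88 lower in knockout hindlimbs (limma). The count was 68 and 60 without knockout forelimb replicates 1 and 3, and 73, 79 and 70 without knockout hindlimb replicates 8, 9 and 10. It was 13 with the male arrays only, 79 with all probe sets tested and 210 with array weights. Of the genes lower in hindlimbs, 61 were shared between the 496 of wild type and the 88 of knockouts, against 2.189 for independent lists, and 21 of the higher genes were shared against 0.27. Of the 650 wild-type calls, 618 had the same sign in knockouts and 606 changed less there, with a median ratio of knockout to wild-type change of 0.491. Of the 123 knockout calls, 120 had the same sign in wild type and 79 changed less there, with a median ratio of wild-type to knockout change of 0.866. Genes chosen for a large change in 1 genotype tend to show a smaller one in the other. The genes are not independent replicates, and the test of the difference itself is the one given above for the genotype effect in each limb type.

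Left and right limbs did not differ in any gene after adjustment. The limma fit with side as the tested term called 0 genes, the smallest adjusted p was 0.223, and 1889 genes had an unadjusted p under 0.05. That is a larger share of the 19936 genes than the 0.05 that chance gives on average, and its cause was not tested. The count was 1 when all probe sets were tested and 1 without wild-type hindlimb replicate 10.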

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

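The tests in this part were set before their results were seen, except that the covariate for the axis of variation within groups and the fit without the 2 apart arrays were added after seeing the data, as was the comparison of that axis with the lists. The patterns on gene neighbours and on Glo1 were noticed in the same data and are hypotheses.

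Forelimbs gave 253 genes between genotypes and hindlimbs 46, a ratio that a difference in maturity, in sex or in the share of muscle might produce. With the axis of variation within groups as a covariate, meant as a measure of maturity, the ratio was 2.44 (151 against 62 genes), and with the Y-linked level it was 3.09 (139 against 45). The Y-linked result stayed above 1.5, the bound set in advance, and argues against sex as the whole cause, but the axis followed the epidermis list within groups (r = 0.978 and rho = 0.979, permutation p = 1e-05 for each, the smallest that the permutations can give, adjusted p = 0.00015 over 30 lists, r = 0.977 without the 2 farthest of 20 arrays) more closely than the early-stage list (r = -0.727, permutation p = 0.00038, adjusted p = 0.00142; rho = -0.735, permutation p = 0.00033, adjusted p = 0.0011; r = -0.684 without those 2), so it does not measure maturity alone and maturity stays open. The axis was built on these same arrays from genes with mean log2 over 6, list members of that level included. The p-values for the lists therefore do not test an independent association. With the muscle list as a covariate the ratio was 0.78 (42 against 54 genes), as a smaller share of muscle in knockout forelimbs would give, while the median size of the 253 changes went from 0.477 to 0.337 and their median SE from 0.096 to 0.113. A lower share of muscle therefore stays open, as does an effect of Lmx1b on forelimb muscle, which the design cannot set apart from it.

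Genes changed by genotype lay next to each other more often than random placement gave. Of 405 placed genes, 22 adjacent pairs changed the same way, such as Dcn with Lum and Lum with Kera, against a median of 5 and a highest count of 17 in random placements, and 0 of 10000 placements gave as many. Overlapping gene models or shared probes might link neighbours, but without overlapping spans and shared name stems 19 pairs were left, and again 0 of 10000 placements reached that (highest 15; 14 when matched on level). A stem is the name without its last number. Related neighbours such as Col3a1 with Col5a2, or Dcn, Lum and Kera, therefore stayed among the 19. Emx2 fell by 1.32 and its neighbour Rab11fip2 fell by 0.42, and E330013P04Rik beyond it fell by 1.94; both neighbours were chosen after their values were seen. Shared regulation of neighbouring genes and shared cell types stay open and were not tested.

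Glo1 rose by 0.61 in knockout limbs with a spread within groups larger than that of 99.4% of the 500 genes nearest in level. That spread was taken over wild-type and knockout groups together, and a uniform shift in knockouts would leave it unchanged. It therefore cannot decide whether the effect of the knockout was uniform. With the Y-linked level as a covariate it rose by 0.678 and kept its call, which argues against sex. A copy number difference of the segment, of a kind known to segregate in some inbred mouse strains, might raise Glo1 in part of the arrays, and its neighbour Btbd9 (0.29, adjusted p = 0.0326) followed Glo1 within groups over 20 arrays with r = 0.868 (permutation p = 1e-05, the smallest that the permutations can give) and rho = 0.653 (permutation p = 0.002). The r was 0.822 without the 2 farthest arrays, the 95th percentile over 19835 neighbouring pairs was 0.586, and the other genes within 3 places gave 0.67 (Dnah8), 0.632 (Glp1r), 0.061 (Mdga1), -0.035 (Umodl1) and -0.262 (Zfand3), where Dnah8 and Glp1r had low mean log2 levels (4.28 and 4.33) and did not pass the test between genotypes (adjusted p = 0.257 and 0.509). Copy number was not measured, so this stays a candidate explanation, and these 6 neighbours were chosen after their values were seen.

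Other splits of the arrays show how often a random division gives as many genes, from 100 splits in each comparison, with the real split counted. The smallest share possible is therefore 1 of 100. The splits treated the arrays as independent, although some limbs may share an embryo, and they did not hold sex fixed. For the genotype over both limb types (406 genes) only 1 split gave as many, the highest other being 1, for hindlimbs (46 genes) 1 split with the highest other 2, and for limb type in wild type (650 genes) 1 split with the highest other 17. In these, no other split drawn reached the real count. For forelimbs (253 genes) 2 splits gave as many, with the highest other 347, for the difference between effects (4 genes) 2 splits with the highest other 15, and for limb type in knockouts (123 genes) 2 splits with the highest other 284, each a share under 0.05. The forelimb split with 347 genes exchanged wild-type replicate 1 and knockout replicate 5, and the split with 284 genes exchanged knockout forelimb replicates 2 and 5 with knockout hindlimb replicates 7 and 8. What sets the exchanged arrays apart was not tested. Without wild-type forelimb replicate 1 the real forelimb comparison itself gave 436 genes. For left against right (0 genes) all 100 splits gave as many, with the highest other 1, which a real count of 0 gives by construction, so that count decides nothing.

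Of 436 groups of 5 arrays over 109 genes, 29 held an array far from the other 4, where chance gives about 1 in 20 groups. The values are log2 intensities. In wild-type forelimb replicate 1, Apod (6.741), Ibsp (3.945), Ckm (5.161) and Rtl3 (8.039) lay below the other arrays and Hmga2 (8.14) above them. In wild-type forelimb replicate 5, Car14 (5.614) and Tbx4 (5.58) lay below and Hoxc9 (4.624) above, and in replicate 2 Sp7 (5.59) lay above. In wild-type hindlimb replicate 9, Thbs4 (5.451), Dcx (6.115), Rspo3 (6.375), Hhip (5.267) and Bgn (7.009) lay below and Lin28b (5.406) above. Cntn1 lay below in wild-type hindlimb replicate 6 (3.824) and Ube2c in replicate 8 (7.494). In knockout forelimb replicate 4, Lhx9 (8.162), Aldh1a2 (9.574) and Msx1 (8.504) lay above and Tnnt2 (7.707) below, and in replicate 3 Calb1 (5.272) lay above. In knockout hindlimb replicate 6, Bmp2 (7.308), Pitx1 (8.222) and Tbx4 (7.275) lay below. In knockout hindlimb replicate 7, Col3a1 (10.283), Tnnt3 (7.472) and Panx3 (5.261) lay above, and in replicate 10 Glo1 (9.107) lay below.

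The genotype effect differed between limb types, by the test of the difference itself, for Grm7 (0.8118), Alx1 (0.8312), Pax1 (0.6641) and Cntn1 (0.8218). Alx1, Pax1 and Cntn1 lost that call in 5, 8 and 15 of 20 fits that left out 1 array, and the other limits are given above. Of 13722 probe sets without a single gene name, which the gene comparisons did not use, 24 changed between genotypes over both limb types (limma, adjusted p under 0.05), 14 higher and 10 lower.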

How the results depend on the processing

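The male arrays only, the covariate for the axis within groups and the fit without 2 knockout arrays were chosen after seeing the data, and the other alternatives before. Counts are genes past the threshold in limma, in the order genotype over both limb types (406), genotype in forelimbs (253), genotype in hindlimbs (46), the difference between these effects (4), limb type in wild type (650), limb type in knockouts (123) and side (0), and each sentence gives counts that moved by more than 1.5 times. The cause was not tested, except where fewer arrays, more tests or a stricter threshold give lower counts by construction.

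With the male arrays only, the counts were 67, 37 and 13 for genotype, 0 for the difference, and 419 and 13 for limb type. With the muscle list as a covariate, the genotype counts were 111 over both limb types and 42 in forelimbs, and 0 for the difference. With the axis within groups as a covariate, forelimbs gave 151 and limb type in wild type 232. With the Y-linked level, forelimbs gave 139, and fitted alone they gave 163. Array weights gave 768 for genotype over both limb types, 82 in hindlimbs, 9 for the difference, and 1260 and 210 for limb type. Testing all probe sets gave 0 for the difference, 427 and 79 for limb type and 1 for side. Centring on the median gave 255 over both limb types. Quantile normalisation and leaving out low-level genes each gave 2 for the difference. Adjusted p under 0.01 gave 161 over both limb types, 90 in forelimbs and 0 for the difference, whose smallest adjusted p was 0.0138, and was not run for limb type, while a minimum of 1.5-fold gave 48, 77 and 24 for genotype and 155 and 40 for limb type. Without the 2 apart knockout arrays no count moved by more than 1.5 times (366, 235, 37, 4, 803, 94 and 0).

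The numbers in the labels do not pair the arrays. Of 10 pairs that share a title number, correlations within groups ran from -0.395 to 0.368, and of 10 that share side and description number from -0.251 to 0.432. A fixed block by side and description number gave 0 for the difference and 78 for limb type in knockouts. The description number as a random block gave 651 over both limb types, with a consensus correlation of -0.0517, and averaging limbs by it gave 106.

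Leaving out each array in turn gave 260 to 595 genes over both limb types, 124 to 436 in forelimbs, 33 to 54 in hindlimbs, 1 to 10 for the difference, 311 to 848 and 60 to 140 for limb type in wild type and knockouts, and 0 to 1 for side. The lowest and highest came without wild-type hindlimb replicate 7 and wild-type forelimb replicate 1 over both limb types. Lmx1b fell in all of them and in every other alternative fit in which it was tested, although its change in the main fit lay under the 1.5-fold minimum.

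Of 237 named gene results, none changed direction. The male arrays alone ended 123 calls, the axis covariate 59, the Y-linked covariate 32 and leaving out the 2 apart arrays 25, while array weights ended 0. The muscle covariate ended 76 of 121, and averaging limbs by description number 34 of 61. Of 2128 set tests of the called lists, 1896 kept the call, 230 kept the direction but lost the call, and 2 reversed. The skeletal muscle list in forelimbs reversed with its own mean as a covariate (camera, adjusted p = 0.992), which that covariate brings about by construction. The epidermis and apical ridge list reversed for limb type in wild type with the axis covariate (camera, adjusted p = 3.76e-06), where the cause was not tested. Signal over background limits genes of low level: 116 of the 406 had a mean log2 under 5.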

Other observations

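Camera called 4 gene groups slightly higher in knockout limbs, and none of these calls held with an estimated correlation. Of 17 hypoxia and glycolysis genes none passed the test, also when adjusted over the list alone, yet the list was called higher over both limb types (median 0.12; camera, adjusted p = 7.09e-05; adjusted p = 0.313 with an estimated correlation). The highest list means were those of knockout hindlimb replicate 6 and knockout forelimb replicate 5, which lay 0.465 and 0.269 above the mean of all arrays, and the call was lost without both (adjusted p = 0.0775). Of 25 cell cycle genes 1 rose, 3 when adjusted over the list alone (median 0.09; camera, adjusted p = 8.37e-07; adjusted p = 0.278 with an estimated correlation). Of 13 genes of earlier stages 2 rose, 4 when adjusted over the list alone (median 0.11; camera, adjusted p = 0.000253; adjusted p = 0.0932 with an estimated correlation). Of 17 Hox genes none passed the test (median 0.16; camera, adjusted p = 0.0023; adjusted p = 0.156 with an estimated correlation).

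Camera called the peripheral nerve, joint and growth factor lists slightly lower, and none of these calls held with an estimated correlation. Of 14 Schwann cell and peripheral nerve genes 1 fell, 3 when adjusted over the list alone (camera, adjusted p = 0.00077; adjusted p = 0.183 with an estimated correlation). Of 16 joint interzone genes 1 fell, also 1 when adjusted over the list alone (camera, adjusted p = 0.0258; adjusted p = 0.281 with an estimated correlation). Of 25 FGF and hedgehog genes 1 fell, again 1 when adjusted over the list alone (camera, adjusted p = 0.019; adjusted p = 0.354 with an estimated correlation). The joint call was lost without wild-type forelimb replicate 2 (0.0619), knockout forelimb replicate 2 (0.0701) or knockout hindlimb replicate 6 (0.137). The FGF and hedgehog call was lost without knockout forelimb replicates 2 (0.0701) or 5 (0.0547) or knockout hindlimb replicate 6 (0.113). The 1 FGF and hedgehog gene was Hhip, which encodes a hedgehog-binding protein and fell by 0.49 (SE 0.103; limma, adjusted p = 0.0126).

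The lists that camera did not call over both limb types included epidermis and apical ridge (0 of 30 genes; adjusted p = 0.559), erythroid cells (0 of 10; 0.059), muscle connective tissue (0 of 11; 0.175), pericytes and smooth muscle (0 of 12; 0.613), podocyte genes tied to Lmx1b (0 of 7; 0.559) and sex-linked genes (0 of 4; 0.403). Of 17 hair follicle, nail and pad genes 1 rose, 2 rose and 3 fell when adjusted over the list alone (0.667). Of 22 immediate early and stress genes 1 fell (0.453), and of 16 limb-type identity genes 3 fell (0.0846). Adjusted over the list alone, 3 erythroid genes fell and 1 rose.

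On the second principal component of 8183 genes, which held 13.5% of the variance, knockout hindlimb replicate 6 (13.91) and knockout forelimb replicate 5 (6.32) stood apart from the other knockout arrays of their groups. Wild-type forelimb replicate 5 (6.46) also stood apart from its group (-6.12 to 1.56), and it was kept in the fit without 2 apart arrays.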
